A study of Mus musculus with 2 samples.

How the data were processed

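The series held total RNA-seq of adrenal gland from 2-month-old female B6CASTF1/J mice, as 2 libraries labelled as biological replicates 1 and 2 of the same tissue. Per the labels' protocols, 300 ng of RNA entered each library, ERCC spike-ins for stranded, ribosomal RNA reduced libraries were used, and the linked documents are those of a tissue RNA purification kit and a directional library kit. The labels conflict on the animals, since the library descriptions name the same animal number for both samples, the biosample descriptions name different numbers, and the donor entry is the same. The labels' biological replicate numbers were followed.

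For each library there was a gene table, a transcript table from the same source and a second transcript table. Per the deposited text that lists the files, all used the mm10 assembly and the GENCODE M21 annotation, the gene table and its transcript table were derived from alignments to the transcriptome, and the second transcript table was derived from the reads and a transcript index. Column names of the file headers are those written by RSEM for the first pair and by kallisto for the second. The aligner, program versions, settings and filters were not given in the sources used here. The authors deposited an expected count per gene and per transcript, an estimated number of read pairs that need not be whole where reads are shared. The deposited TPM values are relative transcript numbers with a fixed sum over all rows of a file, spike-ins included. The deposited percent of a gene's TPM in each transcript is given per the file headers in the transcript table. The other deposited values used were the lower and upper bounds of a TPM interval per gene, whose level is not given in the sources used here.

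Rows were named by matching gene identifiers to GENCODE M21, and all 55536 annotated genes were matched. A symbol of a fixed list with several gene identifiers was taken as the identifier with the highest mean TPM. Gene spans are those of that annotation on mm10. The gene tables also held 96 ERCC rows, 1 phiX row with 0 counts and 26248 rows whose identifier is only a number, which held 5.79 counts in animal 1 and 1 in animal 2. Rows that name no gene stayed out of library sizes and ratios. No column of per-sample values was left unused by a mismatch with the labels.

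Expected counts were rounded to whole numbers for the chi-square test, the dispersion and the scaling factors, and used as deposited for ratios. Scaling used the trimmed mean of M-values of edgeR, with factors of 1.02 and 0.978. Log2 ratios of animal 2 over animal 1 used a prior of 0.5 counts. Intervals at 95% were exact Clopper-Pearson binomial intervals of the share of a gene's counts in each library, turned into ratios. A ratio against 0 counts was given as a bound against a floor of 3 counts per library, which is not the limit of its 95% interval. Genes counted as detected had at least 1 TPM, and correlations across genes used log2 of TPM plus a pseudocount of 1 over genes at 1 TPM in at least 1 library. Genes over 2-fold apart were counted among those with a mean of at least 100 counts. Levels are TPM, which divide by length and are not rescaled between libraries, so the TPM of a gene and its ratio of scaled counts need not move alike.

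The biological coefficient of variation was estimated with edgeR under an intercept-only design, on 16570 genes that passed its expression filter. The gene lists for cell types, zones, states and adjoining tissues were fixed before the data were examined, as were the tests, the rule for named genes and the first set of alternatives. For each list, members with a mean of at least 10 counts were used, the median log2 ratio was taken, and its percentile was found among 10000 random lists of the same size, drawn from genes matched on mean expression in 20 bins. A list was said to stand apart below percentile 2.5 or above 97.5. The percentiles describe these libraries and are not p-values. Tests between groups were not made, because the labels give 1 group.

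The text names members of a fixed list in that list's account, by default the 4 most and 2 least abundant. Some members are not reported here, though the list values include them. It names the 20 genes of highest mean TPM outside the mitochondrial genome and spike-ins, the 10 genes with the largest ratio in each direction among those with at least 100 mean counts, and, of fixed-list genes at 10 TPM or more, the 5 with the largest difference between the quantifications and the 5 with the largest difference between the animals in the share of their leading transcript. Any other gene is said to be chosen after its values were seen.

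The steps were tested on simulated data for the comparison of animal 2 with animal 1, with counts drawn for 55536 genes from the real means and library sizes, a coefficient of variation of 0.2 and 200 genes changed, 100 of them 4-fold and the rest 2-fold. All 100 genes changed 4-fold came out over 2-fold apart. Their median log2 ratios were 2.05 and -1.93, far past the 2-fold limit, so this could hardly fail. It does not say how many unchanged genes pass that limit. The estimated coefficient of variation was 0.216. Of 100 unshifted lists of 12 genes 6 lay outside the central 95%, and of 100 lists shifted by 0.5 on the log2 scale 83 lay past the upper bound.

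Alternatives were size factors of DESeq2, TPM with no further scaling, scaling on spike-in counts, other minimums of counts and TPM, other pseudocounts, shares of counts in place of TPM, the second quantification summed to genes, and each library left out. Added after the data were seen were correction of ratios for transcript length and GC content, restriction to protein-coding genes or to genes with whole counts, and the mitochondrial share with the chromosome 1 pseudogenes. The programs were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0. Reads were not used, so parental alleles were not separated and strand was not examined.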

Results

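Total RNA from whole adrenal glands of 2-month-old female B6CASTF1/J mice, the F1 hybrid of C57BL/6J and CAST parents, was sequenced after ribosomal RNA reduction with ERCC spike-in RNA added. The series held 1 group of 2 biological replicates, called animal 1 and animal 2 here, with 1 library each from 300 ng of RNA. The libraries held 34517566 and 36234838 expected counts on 55536 annotated genes, the spike-ins and a set of further rows. In animal 1, 13254 genes reached 1 TPM (length-scaled transcript abundance), and in animal 2, 13316 did. A gene at 0 counts could hide up to 3 counts, which is 0.0877 CPM in animal 1 and 0.0834 CPM in animal 2. Levels are given as mean TPM ± SD over the libraries (n = 2). Ratios between the animals come from scaled counts, with 95% intervals where given. These intervals and floors covered counting error only, and reads of PCR libraries are not independent molecules. With 2 animals of 1 group no p-value was given between them, since an exact two-sided sign test on 2 libraries cannot go below p = 0.5. Genes are not independent replicates. Counts of genes that share reads with paralogs or pseudogenes were not whole numbers, and their levels and ratios were uncertain.

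The first question was which transcripts made up the adrenal transcriptome. Nuclear protein-coding genes took 64.8% and 64.6% of the counts in animals 1 and 2. The mitochondrial rRNAs took 11.1% and 11.2%, and the mRNAs of the mitochondrial genome 5.36% and 8.77%. Rn7s1 and Rn7s2, which encode 7SL RNA of the signal recognition particle, together held 6.73% and 3.74% of counts. Their reads could not be told apart, so each was given the same level of 133715 ± 44656 TPM. Rn7sk, the 7SK RNA that restrains transcription elongation, stood at 49104 ± 6795 TPM. The whole mitochondrial genome took 19.1% ± 4.54 of TPM (n = 2), at 15.9% in animal 1 and 22.4% in animal 2. By counts its shares lay closer together, at 16.5% in animal 1 and 19.95% in animal 2. The 7SL genes took 33.1% of TPM in animal 1 and 20.4% in animal 2. As TPM has a fixed sum, the larger 7SL share left less TPM for all other rows in animal 1. The ERCC spike-ins took 1.14% ± 0.0440 of TPM, and 72 and 71 of their 96 rows had counts.

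**Figure D1:**
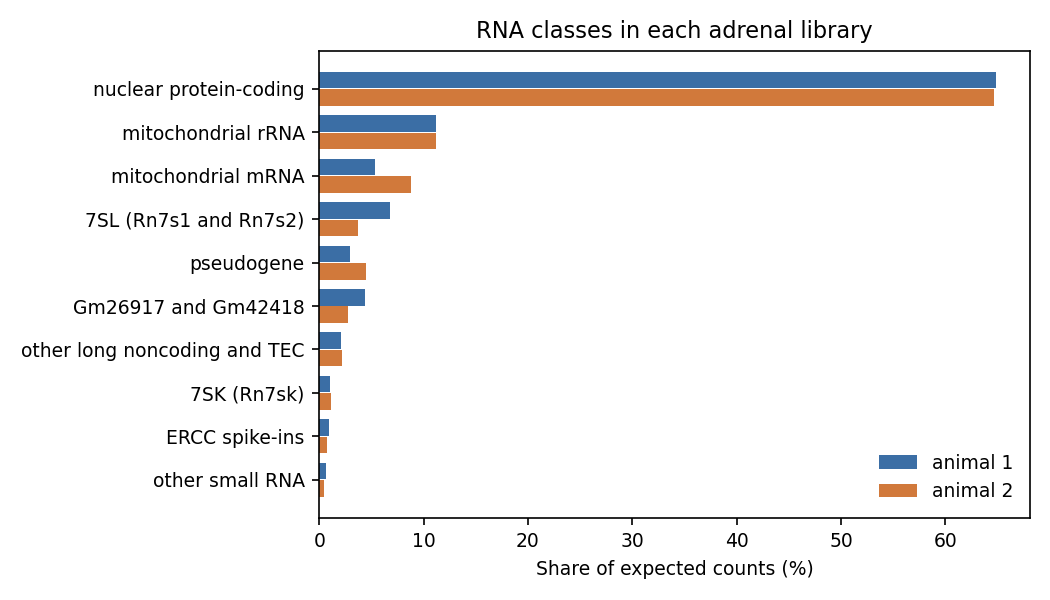
Share of expected counts (%, horizontal bars from 0) in each class of RNA, with 1 bar per animal. Nuclear protein-coding genes took 64.8% and 64.6% in animals 1 and 2, while mitochondrial mRNA took 5.36% and 8.77%, and 7SL RNA took 6.73% and 3.74%.

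The 20 most abundant genes outside the mitochondrial genome and the spike-ins took 42.8% ± 5.71 of TPM (n = 2), against 19.2% of counts and 13.1% of TPM in the second deposited quantification. Beside the 7SL and 7SK genes they included 4 chromosome 1 copies of mitochondrial sequence. These were Gm28661 (19743 ± 7554 TPM), Gm10925 (16687 ± 7245), Gm28437 (11196 ± 4956) and Gm29216 (5826 ± 3180), which share sequence with the mitochondrial genome. Gm26917 (13401 ± 1870 TPM) and Gm42418 (2671 ± 703 TPM) lay side by side on chromosome 17, and a synonym of Gm42418 names it as an 18S rRNA related sequence. Rpph1 (6945 ± 64.0 TPM) and Rmrp (5509 ± 150.1 TPM), the RNA parts of RNase P and RNase MRP, Malat1 (4966 ± 1261 TPM), a nuclear long noncoding RNA, and the small nucleolar RNA Gm22988 (2715 ± 626 TPM) followed. The Rmrp value is that of 1 of its 2 overlapping gene models. Both models summed to 7516 TPM in animal 1 and 5797 TPM in animal 2. The protein-coding genes among the 20 were Star, Hsd3b1, Cyp21a1, Cyp11a1 and Cyp11b1, with Eef1a1 (2841 ± 831 TPM), a translation elongation factor, and Adh1 (2562 ± 462 TPM), an alcohol dehydrogenase.

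Steroid-making enzymes of the adrenal cortex were among the most abundant nuclear protein-coding transcripts. Star, which moves cholesterol into mitochondria, ranked 1 at 4378 ± 362 TPM (n = 2). Hsd3b1, the 3 beta-hydroxysteroid dehydrogenase of the adrenal, had 4155 ± 657 TPM, and Cyp21a1, the 21-hydroxylase, had 3591 ± 382 TPM. Cyp11a1, which cleaves the cholesterol side chain, had 2394 ± 138 TPM, and Cyp11b1, the 11 beta-hydroxylase of corticosterone synthesis, had 2198 ± 412 TPM. The electron carrier Fdx1 was at 776 ± 123 TPM, while Por (114 ± 17.2) and Hsd3b6 (27.9 ± 2.16) were the least abundant of the 10 enzymes and partners. Together the 10 took 1.81% ± 0.156 of TPM, and 5.39% ± 0.0253 of the TPM of nuclear protein-coding genes. By counts their share was 3.52%. Of the 10, 5 were higher in animal 2 and 5 in animal 1, and their median log2 ratio of animal 2 over animal 1 was 0.02, at percentile 28.55 of random lists of like expression, and -0.02 in the other quantification.

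On mm10 with GENCODE M21, Star (ENSMUSG00000031574.8) lies on chromosome 8 from 25806555 to 25815982. Hsd3b1 (ENSMUSG00000027871.16) lies on chromosome 3 from 98852194 to 98859794, and Cyp21a1 (ENSMUSG00000024365.9) on chromosome 17 from 34801348 to 34804561. Cyp11a1 (ENSMUSG00000032323.13) lies on chromosome 9 from 58006411 to 58027023, and Cyp11b1 (ENSMUSG00000075604.5) on chromosome 15 from 74834125 to 74841643. These spans are whole gene models, and the values are sums over each gene's exons.

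Genes of the cortical zones were detected throughout. The ratio of Cyp11b1 to Cyp11b2, the aldosterone synthase of the zona glomerulosa, was 12.1 in animal 1 and 26.0 in animal 2, a log2 ratio of 4.15 ± 0.78 (n = 2), and 5.15 when counts were used in place of TPM. Cyp11b2 itself stood at 127 ± 44.0 TPM and was 1.76-fold higher in animal 1 (interval 1.70 to 1.82). It shares sequence with Cyp11b1, and its counts were not whole. Among all 13 zona glomerulosa genes, Kcnk3, a potassium channel, had 380 ± 63.4 TPM, Dab2 146 ± 28.6 and the angiotensin receptor Agtr1a 97.4 ± 12.5. The least abundant were the ligand Shh (3.20 ± 0.573 TPM) and Agtr1b (2.99 ± 0.134 TPM). In this list 9 genes were higher in animal 1 and 4 in animal 2, with a median log2 ratio of -0.09 at percentile 6.83, which was 0.11 with spike-in scaling and 0.01 with TPM.

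Of the 6 zona fasciculata genes, Akr1b7, an aldo-keto reductase, had 1033 ± 6.26 TPM and Abcb1b, an efflux pump, 556 ± 9.16 TPM. Mrap, the accessory protein of the corticotropin receptor, had 390.3 ± 19.3 TPM. The receptor Mc2r (103 ± 27.3 TPM) was 1.37-fold higher in animal 2, and Nr0b2 (18.1 ± 6.50 TPM) 1.58-fold. The list had 4 genes higher in animal 2 and 2 in animal 1, with a median of 0.15 at percentile 82.33. The X zone, a transient inner layer of the mouse cortex, was represented by 3 genes. Akr1c18, which inactivates progesterone, reached 1990 ± 468 TPM and ranked 8 among nuclear protein-coding genes. It lies on chromosome 13 from 4132615 to 4150654. It was 1.49-fold higher in animal 1, and Pik3c2g (21.6 ± 4.96 TPM) was 1.54-fold higher there, whereas Thrb (39.5 ± 8.66 TPM) was 1.16-fold higher in animal 2. The X zone median was -0.58, at percentile 0.105.

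Sex steroid enzymes were scarce apart from Srd5a2, a steroid 5 alpha-reductase, at 48.4 ± 3.46 TPM. Cyp17a1, the 17 alpha-hydroxylase that the mouse adrenal is known to express little of, had 19 and 33 counts (0.45 ± 0.184 TPM). Cyp19a1, aromatase, had 0 counts in both libraries. Of the 7 genes 2 reached 1 TPM in both libraries and 4 had enough counts for a ratio, with 1 higher in animal 2 and 3 in animal 1. Their median was -0.16 at percentile 20.31, and 0.04 with spike-in scaling.

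Cholesterol supply genes showed high levels of uptake and storage transcripts. Scarb1, the HDL receptor, had 849 ± 52.1 TPM, Soat1, which esterifies cholesterol for storage, 423 ± 87.7 TPM, and Apoe 384 ± 4.95 TPM. The hormone-sensitive lipase Lipe had 111 ± 25.8 TPM. Stard3 (7.33 ± 0.184 TPM) and Abcg1 (1.77 ± 0.0495 TPM) were the least abundant of the 12. In this list 8 genes were higher in animal 2 and 4 in animal 1 (median 0.05, percentile 50.85). Cholesterol synthesis genes differed in that 18 of 20 were higher in animal 1 with the scaling used here, at a median of -0.19 and percentile 0.03, although the median was 0.00 with spike-in scaling. Fdps (259 ± 55.8 TPM), a prenyl transferase, was 1.46-fold higher in animal 1, and Hmgcs1 (246 ± 41.6 TPM), the HMG-CoA synthase, 1.36-fold. Dhcr7 (296 ± 47.8 TPM), the last step of one branch, was 1.09-fold higher in animal 2.

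Regulators of the cortex were led by Nr5a1 (258 ± 10.7 TPM), the nuclear receptor that defines steroid-making cells, with Cyb5a (191 ± 32.5 TPM) and Prkar1a (139 ± 4.28 TPM), a regulatory subunit of protein kinase A. Nr0b1 was at 4.62 ± 0.00707 TPM and Hsd11b2, which inactivates corticosterone, at 0.125 ± 0.00707 TPM. Of the 15 genes measured, 14 had enough counts for a ratio and split 7 and 7 (median 0.01, percentile 40.65, -0.03 in the other quantification). Nr4a1, an immediate early nuclear receptor, stood apart, as it was 2.87-fold higher in animal 2 (interval 2.78 to 2.96).

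The next question was how the medulla was represented beside the cortex. The leading catecholamine enzymes of the chromaffin cells were present at lower levels than the leading steroid enzymes. Th, the rate-limiting enzyme of catecholamine synthesis, had 197 ± 17.9 TPM, Dbh, which makes noradrenaline, 130.5 ± 13.7 TPM, and Pnmt, which makes adrenaline, 130.1 ± 29.8 TPM (n = 2). The steroid enzymes summed to 5.69 times the catecholamine and granule genes in animal 1 and to 7.05 times in animal 2, a log2 ratio of 2.66 ± 0.22. The 11 catecholamine genes took 0.0668% ± 0.00690 of TPM and 0.122% of counts. Of them, 10 were higher in animal 1, among them Pnmt by 1.48-fold, Dbh by 1.23-fold, Th by 1.21-fold, and the least abundant members Slc18a2 (4.59 ± 1.39 TPM), a vesicular transporter, by 1.65-fold and Slc6a2 (3.92 ± 1.12 TPM), the noradrenaline transporter, by 1.61-fold. The median log2 ratio was -0.39, below the 10000 random lists (percentile 0).

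Granule and neuroendocrine genes went the same way. Chgb (637 ± 112 TPM) and Chga (554 ± 62.1 TPM), the granins of chromaffin granules, were 1.37-fold and 1.25-fold higher in animal 1. Npy (303 ± 35.0 TPM), a peptide transmitter, was 1.11-fold higher in animal 2, and the carboxypeptidase Cpe had 279 ± 43.8 TPM. Syt1 (3.15 ± 0.247 TPM) and Pcsk2 (1.55 ± 0.170 TPM) were the least abundant of the 19 measured. In all, 17 were higher in animal 1 and 2 in animal 2, with a median of -0.32 at percentile 0.01. Transcription factors and receptors of chromaffin cells, led by Epas1 (55.7 ± 8.66 TPM) and Hand2 (10.8 ± 0.233 TPM) and with Ret scarce (0.815 ± 0.0354 TPM), had 10 of 12 genes higher in animal 1. Their median of -0.19 lay at percentile 4.77, inside the central 95% of random lists, and was 0.00 with spike-in scaling.

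Other cells of the gland were compared in the same way. Stromal genes were led by Dcn (65.7 ± 9.39 TPM), a matrix proteoglycan, and Nr2f2 (32.7 ± 7.22 TPM), while Gli1 (0.835 ± 0.106 TPM), a marker of capsular progenitors, and Gata4 (0.42 ± 0.113 TPM) were scarce. Of 13, 7 were higher in animal 2 and 6 in animal 1 (median 0.03, percentile 63.78), and the sign turned in the other quantification and after correction for length and GC content (-0.01). Endothelial genes, led by Plvap (66.1 ± 3.50 TPM) of fenestrated vessels and Eng (32.3 ± 3.57 TPM), split 7 and 6 (median 0.02, percentile 53.19, -0.02 in the other quantification). Mural and smooth muscle genes had 8 of 10 higher in animal 2, with a median of 0.19 at percentile 98.85. Tagln had 32.2 ± 5.98 TPM, Mylk 15.9 ± 3.90 TPM, and Acta2 (11.97 ± 3.27 TPM), smooth muscle actin, was 1.53-fold higher in animal 2. Schwann and sustentacular genes were near the detection limit except Pmp22 (56.7 ± 13.2 TPM), with 4 of 11 at 1 TPM in both libraries. Of them 9 were higher in animal 1 (median -0.37, percentile 1.405).

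Immune cell transcripts were few. Macrophage genes were led by the lysozyme Lyz2 (57.6 ± 3.70 TPM) and the complement subunits C1qb (23.2 ± 2.11) and C1qa (21.2 ± 1.82), and 10 of 12 were higher in animal 1 (median -0.23, percentile 1.12). Antigen presentation genes were led by B2m (374 ± 62.5 TPM), the light chain of MHC class I, and H2-K1 (216 ± 22.4 TPM). In that list 6 of 8 were higher in animal 1, H2-D1 by 1.502-fold and H2-K1 by 1.32-fold, with a median of -0.24 at percentile 0.56, whereas the median was 0.08 with TPM. The class I genes are highly polymorphic, and reads of the CAST allele were counted on C57BL/6J sequence. Lymphocyte genes summed to 1.25 and 1.24 TPM over 10 genes, 4 of which were under 0.1 TPM in both libraries, and too few had counts for a ratio.

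Lists for tissues that adjoin the gland or share its blood were measured next. Adipocyte genes were abundant, with the complement factor Cfd at 811 ± 9.998 TPM, the fatty acid binding protein Fabp4 at 759 ± 112 TPM and Car3 at 661 ± 127 TPM. Of 11, 9 were higher in animal 2 (median 0.20, percentile 95.75). Lep, leptin, at 195 and 61 counts, was 3.20-fold higher in animal 1 (interval 2.40 to 4.36). All 6 brown adipocyte genes were higher in animal 2, with a median ratio of 1.97-fold (log2 0.98, percentile 100). Ucp1, the uncoupling protein of brown fat, had 313 ± 164 TPM and was 2.05-fold higher (2.00 to 2.10). Cox8b (389 ± 185 TPM) was 1.89-fold higher, Cidea (134 ± 48.9 TPM) 1.59-fold, Cox7a1 (106 ± 23.8 TPM) 1.30-fold, Elovl3 (14.7 ± 8.41 TPM) 2.23-fold, and Ppargc1a, a coactivator of mitochondrial biogenesis, 4.54-fold (3.94 to 5.28). Erythroid genes had 5 of 6 higher in animal 2 (median 0.60, percentile 99.98). The globins Hba-a1 (618 ± 286 TPM) and Hba-a2 (442 ± 212 TPM) were 1.73-fold and 1.90-fold higher, but share reads, and summed they were 1.79-fold higher.

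Transcripts of kidney, liver and pancreas were higher in animal 1, and most of those of kidney and pancreas stood at low levels. Kap, a protein of the proximal tubule, had 350 counts in animal 1 and 0 in animal 2. Against the floor of 3 counts it was 117-fold lower in animal 2, while its 95% interval began at 94.9-fold. Slc34a1, a phosphate transporter, with 91 and 0 counts, and Umod, uromodulin, with 77 and 0 counts, were 30.5-fold and 25.8-fold lower against that floor. Lrp2, megalin, had 437 and 63 counts and was 6.93-fold higher in animal 1, while Aqp2 had 13 and 12. Of 10 kidney genes 0 reached 1 TPM in both libraries, and 7 had 0 counts in animal 2. The 6 with enough counts were all higher in animal 1. Their median log2 ratio was -5.16 as fitted, at percentile 0, and -3.86 with the 3 members at 0 counts set to their bound. Of 9 liver genes 8 were higher in animal 1 (median -0.89, percentile 0). Alb, albumin, with 100.5 ± 28.1 TPM, was 1.59-fold higher, Ahsg 1.95-fold and the fibrinogen chain Fgb 2.15-fold. Cyp2e1 (84.0 ± 10.7 TPM) was 1.13-fold higher in animal 2. All 9 liver genes reached 1 TPM in both glands.

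Of 8 pancreatic genes, Cela1, an elastase, was present in both libraries at 19.6 ± 1.22 TPM (702 and 622 counts). The chymotrypsinogen Ctrb1 had 27 and 0 counts and was 9.05-fold lower in animal 2 against the floor of 3 counts. Pnlip, pancreatic lipase, had 26 counts in animal 1 and 1 in animal 2, a ratio of 17.8 (interval 4.29 to 1072). The 4 genes with enough counts were all higher in animal 1, with a fitted median of -4.03 at percentile 0, and -3.55 with 1 member at its bound. Skeletal muscle genes (6 of 7 under 0.1 TPM in both libraries, Mylpf highest at 0.74 ± 0.0283 TPM) and ovary genes (4 of 6 under 0.1 TPM, Gdf9 highest at 2.60 ± 0.742 TPM) had too few counts for a list ratio.

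**Figure D2:**
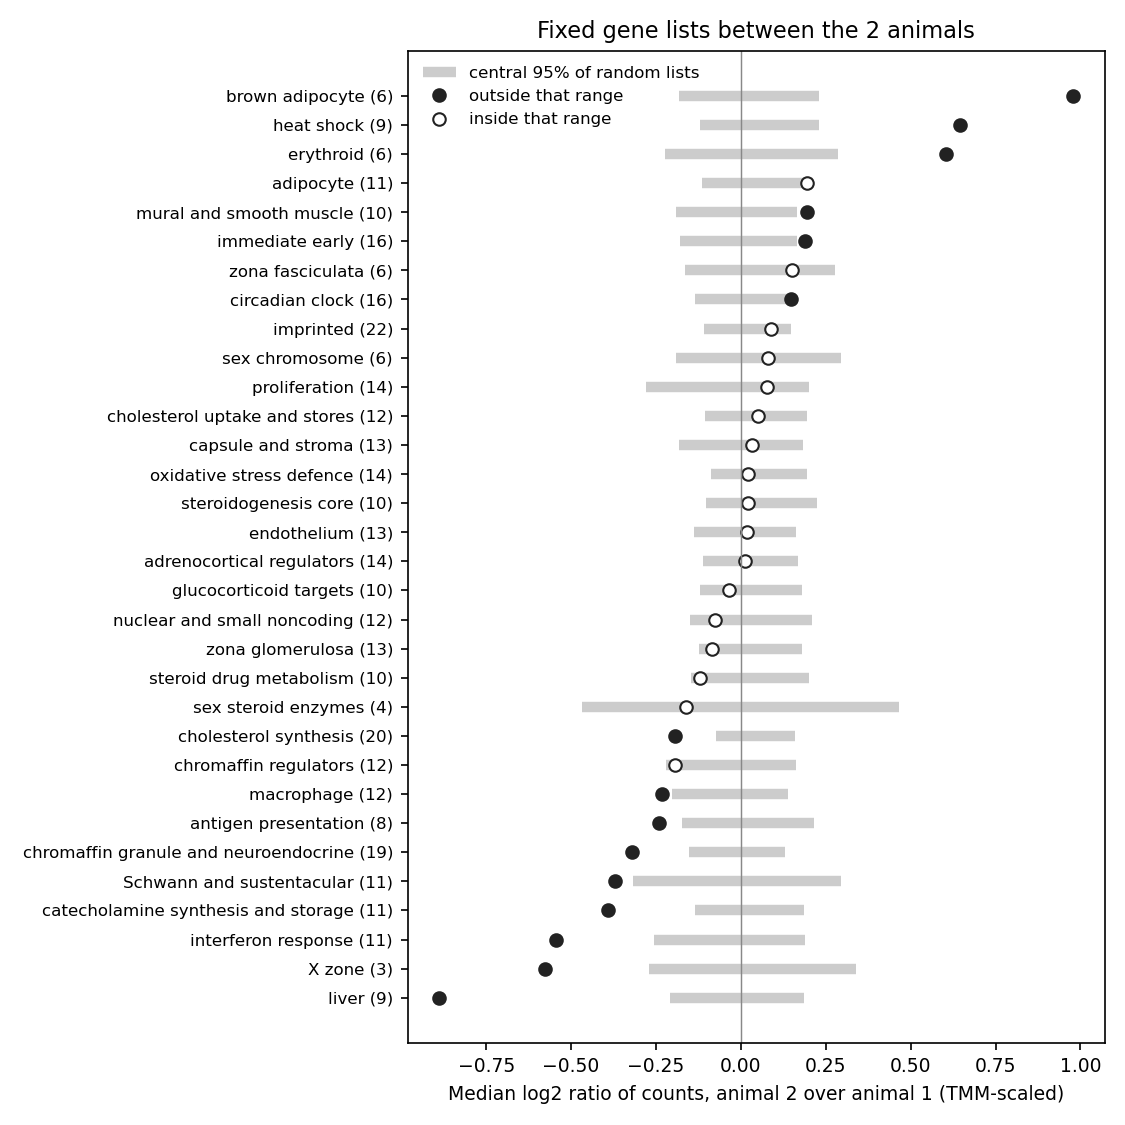
Median log2 ratio of scaled counts, animal 2 over animal 1, for each fixed list (points; number of genes tested in brackets) against the central 95% of random lists matched on expression (grey bars); kidney (-5.16) and pancreas (-4.03) are left out for scale. Brown adipocyte genes lay highest at 0.98 and liver genes lowest of those drawn at -0.89, and 7 lists, such as cholesterol synthesis, zona glomerulosa and chromaffin regulators, flip from below to above 0 with spike-in scaling, which adds 0.20 to every log2 ratio and leaves percentiles as they were, while antigen presentation, zona glomerulosa and glucocorticoid targets do so with TPM.

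Genes that report the state of the tissue also differed between the animals. Heat shock genes had 7 of 9 higher in animal 2, with a median of 0.64 at percentile 100. Hspa8 (1169 ± 403 TPM), a constitutive chaperone, was 1.56-fold higher. Hspa1a and Hspa1b, the near-identical inducible Hsp70 genes, summed to a ratio of 3.73-fold. The mitochondrial chaperones Hspd1 (507 ± 53.7 TPM) and Hspe1 (299 ± 17.4 TPM) were 1.24-fold and 1.16-fold higher in animal 1. All 11 interferon response genes were higher in animal 1, at a median of -0.55 and percentile 0. Irf7, a transcription factor of this response, was 2.03-fold higher (1.73 to 2.38), and Ifi27l2a (123 ± 7.52 TPM) 1.16-fold.

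Immediate early genes went both ways. With Nr4a1, Nr4a3 (46.2 ± 18.7 TPM, 1.41-fold) and Junb (9.67 ± 4.48 TPM, 1.85-fold) were higher in animal 2, while Jun (54.3 ± 9.49 TPM, 1.36-fold), Dusp1 (12.8 ± 1.70 TPM, 1.35-fold) and Fos (1.56 ± 0.679 TPM, 1.94-fold) were higher in animal 1. The list had 9 higher and 7 lower in animal 2, with a median of 0.19 at percentile 98.64, but 0.03 at percentile 69.27 in the other quantification. Circadian clock genes had 13 of 16 higher in animal 2 (median 0.15, percentile 98.15), among them Nr1d1 (43.2 ± 5.31 TPM) by 1.12-fold and Per2 (19.7 ± 5.86 TPM) by 1.44-fold. Glucocorticoid targets split 5 and 5, led by the metallothionein Mt1 (125 ± 16.4 TPM) and with Tsc22d3 at 49.9 ± 4.04 TPM (median -0.03, percentile 20.83, but 0.16 with spike-in scaling and 0.12 with TPM). Proliferation genes were low, with Mki67 at 1.63 ± 0.368 TPM and Pcna, a clamp of DNA polymerase, at 28.2 ± 1.05 TPM, and 11 of 14 were higher in animal 2 (median 0.08, percentile 82.37, but 0.42 at percentile 99.13 with TPM and 0.01 for the 5 genes with at least 100 mean counts).

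Metabolic and defence genes were mostly abundant, and neither list stood apart with the scaling used here. Sod1, superoxide dismutase, had 499.5 ± 10.4 TPM, Gpx4 400.1 ± 110 TPM and Prdx3 294 ± 3.37 TPM, while Txnrd2 (27.4 ± 2.76) and Gsta4 (16.7 ± 0.368) were lowest of the 14. Of these genes 8 were higher in animal 2 and 6 in animal 1 (median 0.02, percentile 29.87, -0.01 in the other quantification). Nnt entered by 1 of its 2 gene models, which share reads, so its direction in this list is uncertain. Both models summed were 1.12-fold higher in animal 2. Of 10 genes of steroid and drug metabolism 7 were higher in animal 1 (median -0.12, percentile 4.74, but 0.08 with spike-in scaling). Under 1 alternative that list stood apart, at percentile 2.46. After Adh1 came Akr1cl (363 ± 29.7 TPM), the cytochrome Cyp2f2 (316 ± 40.2 TPM) and Aldh1a1 (97.2 ± 14.5 TPM), with Akr1c14 lowest at 0.925 ± 0.134 TPM.

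Sex-linked and imprinted genes were measured in both female glands. Xist, the RNA that coats the inactive X chromosome, had 17779 and 24380 counts and was 1.36-fold higher in animal 2. The Y-linked genes Uty, Kdm5d and Eif2s3y had 0 counts in both libraries and Ddx3y had 1 count in animal 1. Ddx3x (176 ± 11.6 TPM) and Eif2s3x (63.2 ± 0.926 TPM) led the X-linked genes, and of the 6 genes with enough counts 4 were higher in animal 2 (median 0.08, percentile 57.68). Of 22 imprinted genes 20 reached 1 TPM in both libraries. Gnas (845 ± 166 TPM), a G protein subunit, the noncoding RNA Meg3 (257 ± 42.4 TPM), Dlk1 (236 ± 27.4 TPM) and the cell cycle inhibitor Cdkn1c (223 ± 13.8 TPM) led them. In this list 13 were higher in animal 2 (median 0.09, percentile 86.16, but -0.06 after correction for length and GC content). Nuclear and small noncoding genes had 8 of 12 higher in animal 1 (median -0.08, percentile 10.96, but 0.12 with spike-in scaling and 0.01 in the other quantification), and Rny3 had 0 counts in both libraries. Rmrp entered this list by 1 of its 2 gene models.

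The last comparison asked how alike the glands of the animals were, and which single genes stood apart. Together 12843 genes reached 1 TPM in both libraries, of which 11797 were protein-coding and 356 of long noncoding classes. Across the 13727 genes at 1 TPM in either, log2 levels correlated at Pearson r 0.971 and Spearman rho 0.971, and at r 0.984 for protein-coding genes. Among 12171 genes with at least 100 mean counts, 167 (1.37%) were over 2-fold apart, 72 higher in animal 2 and 95 in animal 1. That split depended on the scaling, since spike-in scaling, which moved the median log2 ratio of all these genes to 0.19, gave 138 and 66, and TPM, which moved it to 0.11, gave 121 and 93. The other quantification gave 95 and 74. Of the 167 genes 89 were protein-coding, 36 processed pseudogenes and 16 snoRNAs, and 55.1% of them shared reads with other genes against 18.0% of all tested. The quartiles of all log2 ratios were -0.17 and 0.16, and the common biological coefficient of variation was 15.4%. The libraries differed far beyond sampling noise (chi-square per degree of freedom 70.4 over 19040 genes), so they were not copies of 1 library. The test cannot tell 2 animals from 2 preparations of 1 animal. That they are 2 animals rests on the labels' replicate numbers, with which other label entries conflict.

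The genes with the largest ratios were mostly ones that share reads. Higher in animal 1 were Kap, the processed pseudogenes Gm10163, Gm6361, Gm5537 and Trmt112-ps2, the genes Gm45808 and Tmem254c, Snord22, a second gene model of Rmrp (12.4-fold) and the small nucleolar RNA Gm22486. Among these only Kap and Gm22486, 7.54-fold higher in animal 1, had whole counts. In the other quantification Gm10163 was higher in animal 2 (62.9 and 100.2 TPM in animals 1 and 2), and Tmem254c differed less (9.07 and 6.71 TPM). Kap and Gm45808 kept their direction there, and the rest of these were at or near 0. Higher in animal 2 were a second gene model of Nnt, the pseudogenes Pgk1-rs7, Rps13-ps2, Gm12918, Gm10335 and Gm15429, and Fam177a, Gm45130, Ppargc1a and Cyp26b1. Among these whole counts were found for Gm45130 (4.75-fold), Ppargc1a and Cyp26b1, which degrades retinoic acid and was 3.87-fold higher (3.45 to 4.36). In the other quantification Gm10335 was lower in animal 2 (2.57 and 1.35 TPM in animals 1 and 2). Fam177a (6.22 and 6.40 TPM) and the second Nnt model (41.7 and 45.2 TPM) differed little there. Gm15429, Gm45130, Ppargc1a and Cyp26b1 stayed higher in animal 2, and Pgk1-rs7, Rps13-ps2 and Gm12918 were at 0. Cyp26b1 lies on chromosome 6 from 84571414 to 84593908, and Ppargc1a on chromosome 5 from 51454250 to 51567726. Nnt, the mitochondrial transhydrogenase of which C57BL/6J carries a deletion, has overlapping models on chromosome 13. Its second model had 0.15 and 1770 counts, but both models summed to 4414 and 4960 counts, a ratio of 1.12-fold. Both Rmrp models summed were 1.40-fold higher in animal 1.

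**Figure D3:**
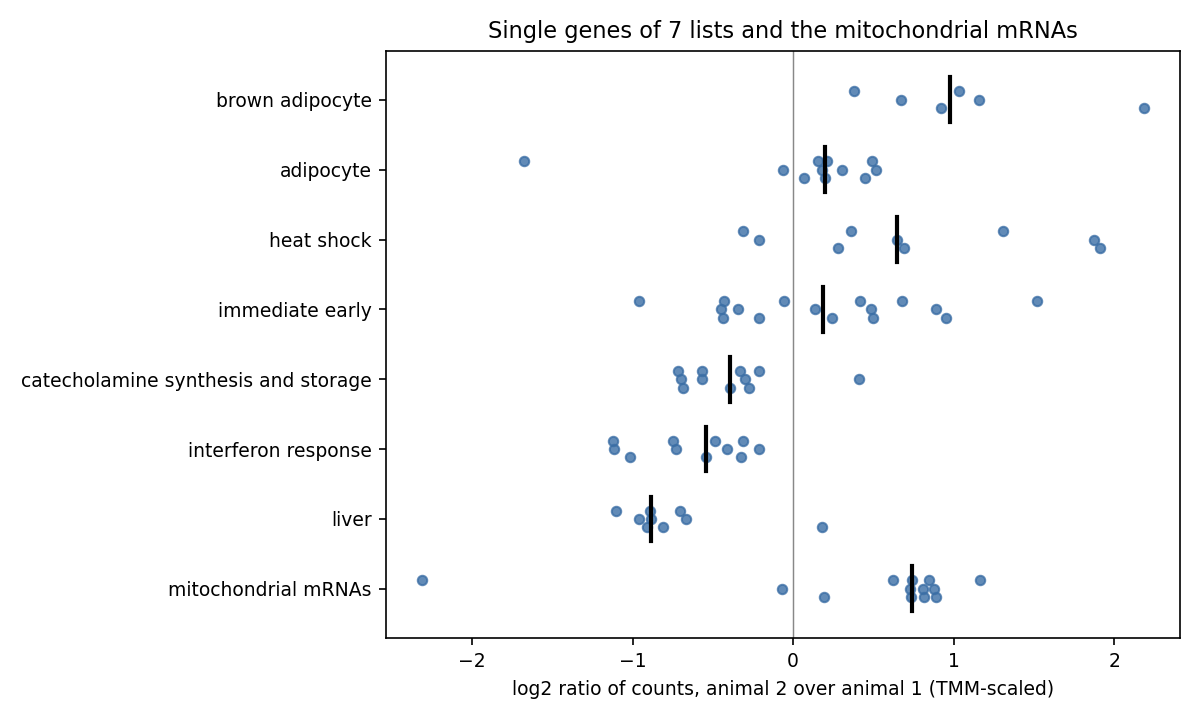
Log2 ratio of scaled counts, animal 2 over animal 1, of each gene (points) in 7 fixed lists and for the mitochondrial mRNAs, with the median of each as a black bar. The 6 brown adipocyte genes all lie above 0 with a median of 0.98, and the 11 interferon response genes all lie below 0 with a median of -0.55.

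Of 37 fixed lists 34 had at least 3 genes with enough counts, and 17 of these lay outside the central 95% of random lists, 6 higher in animal 2 and 11 in animal 1. By chance 1.7 were expected. The Schwann, mural, macrophage, immediate early and clock lists moved inside that range under 1 to 3 of the alternatives run for them, and antigen presentation did with TPM. These percentiles describe the libraries of 2 animals, and members of a list are not independent of each other.

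Transcript forms were compared for the 228 fixed-list genes at 10 TPM or more. In 118 of them (51.8%) the leading transcript took at least 80% of the gene's TPM in both libraries. Of the 228, 34 had a single annotated transcript and so passed by definition. Among the 194 genes with more than 1 transcript, 84 had such a leading transcript. The share of the leading transcript differed between the animals by a median of 2.74 percentage points over all 228, single-transcript genes included. The largest differences were those of Nnt (49.4% and 96.5%), Bst2 (100% and 60.3%), Apoa2 (65.3% and 25.8%), Tagln (56.7% and 96.1%) and H2-Ab1 (94.9% and 56.1%). In the second deposited quantification the same transcript took 98.7% and 97.6% of Bst2, 98.1% and 96.3% of Tagln and 80.6% and 37.0% of H2-Ab1, and another transcript led for Nnt (81.4% and 40.2%) and Apoa2 (53.7% and 38.9%). The differences in Bst2 and Tagln were thus not found there. The Nnt shares are those within 1 of its 2 overlapping gene models, and the other model held 0.15 counts in animal 1 and 1770 in animal 2. The Nnt difference thus cannot be told from reads placed on the other model. That quantification named the same leading transcript for 184 of the 228, single-transcript genes included. Gene levels in the pair of quantifications correlated at r 0.844 in animal 1 and 0.863 in animal 2, and at 0.972 and 0.969 for protein-coding genes. The largest differences were in small RNAs, as Rmrp and Rny1 were listed at 0 in the second quantification, Rn7s1 and Rn7s2 at 2.39 TPM each and Rn7sk at 31.4 TPM. The transcript index of that quantification was not examined, so whether these low values, and with them the lower correlation over all genes and the lower share of the top 20, come from the index stayed open.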

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

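In this part the test of further kidney genes was written before their values were seen, and the other tests were chosen only after the result was seen. In animal 1, 5.79 counts fell on the 26248 rows whose identifier is only a number, which no comparison used. Animal 2 had 1 count there. What these rows stand for was not worked out. Beyond tissue makeup, no biological explanation was tested for the patterns that follow, because the design gives no contrast.

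The mitochondrial mRNAs were higher in animal 2, with 11 of 13 genes and a median log2 ratio of 0.74, while the mitochondrial rRNAs differed by 1.05-fold. The 11 include mt-Co3 and mt-Atp6, whose deposited TPM lay under its own deposited interval in both animals. Reads shared with the 4 chromosome 1 pseudogenes could move counts between copies, but mRNAs and pseudogenes summed had a log2 ratio of 0.78 (interval 0.78 to 0.79), which argues against that source. More mitochondria-rich cells would raise nuclear subunits of oxidative phosphorylation too, yet 81 of these had a median of 0.0326 (quartiles -0.12 and 0.24). A difference in how mitochondrial mRNA was kept, captured or regulated stays open and was not tested.

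Kidney, pancreas and liver transcripts were higher in animal 1. Of the 19 tested members of these lists 17 had whole counts in both libraries, which argues against reads shared with other genes for those 17. Whole counts are usual, as 18.0% of all genes with at least 100 mean counts shared reads. Of 20 further kidney genes 12 had at least 10 mean counts, and their median log2 ratio was -1.002 (quartiles -2.13 and -0.27), with 9 lower in animal 2 and 6 of these over 2-fold. This is consistent with RNA from kidney in the library of animal 1, such as adjoining tissue, as a hypothesis for the kidney part alone, and Kap, the most abundant of the listed kidney genes, stood at 8.23 ± 11.6 TPM. Of the further genes, 2 were over 200 counts in both libraries, so part of that list is expressed in both glands, and tissue carried over at dissection was not told from RNA carried between libraries.

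Brown adipocyte genes were higher in animal 2. More fat of the same makeup would raise the adipocyte and brown adipocyte lists alike. The brown median exceeded the adipocyte median by 0.78 on the log2 scale, against a quartile range of 0.26 among the adipocyte genes. The adipocyte list was not one of white fat markers. In it 9 of 11 genes were higher in animal 2, while Lep was 3.20-fold higher in animal 1. More brown fat beside other fat that differed less, with Cox8b (389 TPM) and Ucp1 (313 TPM) as its most abundant markers, stays open, as does a difference in thermogenic state, and neither was tested.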

How the results depend on the processing

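Alternatives chosen only after the data were seen were those on protein-coding genes, whole counts, length and GC content, and the added mitochondrial pseudogenes. Of 233 alternative list medians 217 kept their side of the bounds, 17 of these with a changed sign in lists that did not stand apart, 11 no longer stood apart, 3 newly did and 2 that stood apart changed sign. The last were cholesterol synthesis with spike-in scaling (0.0043, percentile 0.03) and antigen presentation with TPM (0.0814, percentile 27.62), both still below the median of all genes under that scaling (0.19 and 0.11). DESeq2 and spike-in scaling each add 1 constant to every log2 ratio, so no list could cross the percentile bounds under them. Of 17 lists that stood apart 11 did so under every alternative run for them, and 14 of the other 17 under none. Those that lost it were the Schwann, mural, macrophage, immediate early, clock and antigen presentation lists, and those that gained it adipocyte, proliferation and steroid drug metabolism. Genes over 2-fold apart numbered 6301 of 26370 with no count filter, 36 of 5302 at 1000 mean counts or more and 57 of 9759 protein-coding genes with whole counts, which follows from the genes tested. They numbered 167 with DESeq2 (72 higher in animal 2), 214 with TPM, 204 with spike-in scaling and 169 in the other quantification. Genes detected in both animals ranged from 8662 at 5 TPM to 18471 at 0.1 TPM. Pearson r between the animals was 0.943 with a pseudocount of 0.1, 0.980 with 10, 0.987 with no filter and 0.984 for protein-coding genes. The share of the 20 most abundant genes was 53.6% without mitochondrial, rRNA and spike-in rows, 19.2% of counts, 13.1% in the other quantification and 10.6% among nuclear protein-coding genes. In the same order the steroid share was 2.29%, 3.52%, 2.94% and 5.39%, and the catecholamine share 0.0837%, 0.122%, 0.118% and 0.1997%. By counts the log2 ratio of Cyp11b1 to Cyp11b2 was 5.15 and the spike-in share 0.835%, and the latter was 1.60% in the other quantification. The mitochondrial share was 28.5% in the other quantification and 24.5% with the pseudogenes. The quantifications correlated at 0.753 with a pseudocount of 0.1, 0.933 with no filter and 0.971 for protein-coding genes. A dominant transcript was found in 72.8% of genes at a limit of 60%, 43.0% at 90% and 44.7% in the other quantification. Beyond changes of denominator, length scaling or limit, the cause was not tested. Of 228 gene levels 218 were higher in the other quantification, and of 80 alternative gene ratios 18 moved. Leaving out each library gave ranges of 38.8% to 46.9% for the top 20, 1.70% to 1.93% for steroid and 0.0619% to 0.0717% for catecholamine genes, 2.51 to 2.82 for cortex over medulla, 3.59 to 4.70 for Cyp11b1 over Cyp11b2, 15.9% to 22.4% for mitochondrial, 1.11% to 1.17% for spike-in, 13254 to 13316 detected genes, 0.844 to 0.863 for the quantifications and 54.8% to 58.3% for dominant transcripts. Detected genes and dominant transcripts then had to pass in 1 library in place of both, and the other values lie within 1 SD by construction, so these ranges say nothing about stability. No paired analysis was possible because there is 1 group. More depth would narrow counting error but not the difference between animals.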

Other observations

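In this part the gene families and single genes were chosen after their values were seen. Of protein-coding genes with whole counts, G6pc, the glucose 6-phosphatase subunit, was 3.25-fold higher in animal 2 (interval 2.77 to 3.85), Ppara, a receptor that drives fatty acid oxidation, 2.39-fold (2.15 to 2.67), and Dio2, which activates thyroid hormone, 2.32-fold (2.17 to 2.47). Sik1, a kinase induced by cyclic AMP, was 2.48-fold higher (2.34 to 2.64), and Plau, the urokinase, 2.75-fold (2.498 to 3.04). Higher in animal 1 were Tat, the tyrosine aminotransferase, by 2.89-fold (2.41 to 3.51), Chka, a choline kinase, by 2.66-fold (2.56 to 2.77), and Socs3, an inhibitor of cytokine signalling, by 2.64-fold (2.07 to 3.41). Ppara and Dio2 are also active in brown fat, whose list was higher in animal 2 (median 0.98), and Tat in liver, whose list was higher in animal 1 (median -0.89), but G6pc, a liver gene too, went against that list.

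Among gene families, 55 of 79 cytosolic ribosomal protein genes were lower in animal 2 (median log2 ratio -0.17, percentile 0), as were 27 of 37 proteasome genes (median -0.10, percentile 0.19), and both medians turn above 0 with spike-in scaling (0.03 and 0.10), as that of the proteasome genes does with TPM (0.04), but these scalings also moved the median of all genes tested for 2-fold differences, to 0.19 and 0.11, and both families stayed below it. Of 63 histone genes 53 were lower in animal 2 (median -0.27, percentile 0, and -0.07 with spike-in scaling), and of 35 collagen genes 28 were (median -0.20, percentile 0.03, and -0.01 with spike-in scaling). Across 11512 protein-coding genes the log2 ratio rose weakly with transcript length (Spearman rho 0.132). The families were not corrected for length or GC content, so a part of length in their medians was not tested. Of the mitochondrial mRNAs mt-Atp8 had the highest log2 ratio at 1.16 and mt-Co2 the lowest at -2.31. In the other quantification mt-Atp8 was at 0 TPM in both animals. The deposited TPM of mt-Co2 lay under its own deposited interval in both animals (108.55 against 1397 to 2399 in animal 1 and 23.3 against 1990 to 3684 in animal 2). So did that of mt-Co3 and that of mt-Atp6 (5793 against 6177 to 7009.5 in animal 1 and 11410 against 13846 to 15522.5 in animal 2). The ratios of mt-Co2, mt-Co3 and mt-Atp6 are thus not reliable. Levels of other mitochondrial mRNAs, mt-Atp8 and mt-Co1 among them, lay above their intervals. This was not particular to mitochondrial genes. In animal 1 Star (4122 against 4017 to 4070 TPM) and Rn7sk (44299 against 43307 to 43587 TPM) also lay above their intervals. Hsd3b1, Cyp21a1 and Cyp11b1 did too, while Rn7s1 lay inside its own. The mRNA of mt-Nd6, coded on the other strand, had a log2 ratio of -0.07, while mt-Co1 (14662 ± 5801 TPM) was 1.67-fold higher in animal 2.

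The ERCC spike-ins with at least 100 mean counts numbered 29, and their levels in the libraries correlated at r 0.995, with a median log2 ratio of -0.13 and a range from -0.74 to 0.31. Of the fixed-list genes that code for protein, the largest differences between the quantifications were in Hbb-bt, which was 3.28-fold higher in the second, Cidec at 2.71-fold and Hba-a1 at 2.69-fold. The median log2 level of the second over the first was 0.72 in animal 1 and 0.51 in animal 2.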
